A study of Mus musculus with 18 samples.

How the data were processed

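The data were 18 samples in 18 groups from mouse R1 embryonic stem cells grown on gelatin without feeders in N2B27 with LIF, CHIR99021 and PD0325901. The deposited peak lists of 16 samples were used, 13 from ChIP-nexus and 3 from ChIP-seq, of which 6 belong to the edited-line experiment. The patchcap control and the input control were not used here. The antibodies per the labels were sc-8628 for Oct4, sc-17320 for Sox2, sc-30328 for Nanog, AF3158 for Klf4, ab19331 for Esrrb, sc-888 for Pbx 1, 2 and 3 and ab222124 for Zic3, and in the edited-line experiment ab214549 for Nanog and an Active Motif antibody for Sox2.

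Per the submitters' processing notes, reads were handled with cutadapt 1.8.1, BWA 0.7.13, SAMtools, bedtools and MACS2 2.1.1.20160309 on genome build mm10. The role and order of these tools, the handling of replicates, the control used for peak calling and the caller of the ChIP-seq lists are not given in the sources used here. In the deposited ChIP-nexus lists the signal value is the ratio (fold enrichment) written by the authors' peak caller and the next value is −log10 p. In the deposited ChIP-seq lists the signal value is a score of the authors and no p was filled in. Sequencing depth was not known and no depth correction was made. All peaks lay on chromosomes 1 to 19, X and Y. The Oct4 and Nanog ChIP-seq lists held 6 and 215 repeated intervals, which were kept and joined on merging. No peak was left out.

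Work was done with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, the mm10 reference sequence and the GENCODE vM21 basic annotation. The comparisons, settings, gene lists, motifs and most alternatives were fixed before the data were examined. All intervals are 95% intervals, adjusted values follow Benjamini and Hochberg within each comparison, and the smallest p written is 1e-300.

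Peaks of the 7 factors that share at least 1 bp were merged into regions. Each of the 21 pairs was tested by Fisher's exact test in the regions of the other 5 factors. Numbers expected for several factors are the product of the shares of each factor over all regions. Other pairs of lists were compared in the same way over regions merged from all 16 lists and called in at least 1 list outside the pair. Location was taken from the summit, with promoter meaning within 1000 bp of a coding transcript start.

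The 8 motifs were Oct4-Sox2 (WTTGTNATGCAAA, with up to 1 mismatch), Sox2 (CCWTTGTTC), Nanog (TGATGGC), Klf4 (GCCMCRCCC), Esrrb (TCAAGGTCA), Zic3 (CCTGCTGDG), Pbx (TGTCAMTCA) and CTCF (CCASYAGRKGGC). Matches on either strand within 50 bp of a summit were compared with windows of the same size moved by 1000 bp. Distance from summit to motif was taken at peaks shared by the assays with exactly 1 motif within 100 bp of the middle of the ChIP-nexus and ChIP-seq summits, and tested by an exact binomial test of which summit was closer. Spacing was taken between Nanog motifs, with up to 1 mismatch, at 12 to 150 bp in windows of 100 bp, as spectral power at periods of 10 to 11 bp relative to the mean over 5 to 20 bp. The comparison shifted each match by 0 to 10 bp in 1000 permutations.

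At the edited locus, regions called in wild type and in both mutants were ranked by the authors' signal within each list. The rank shift was compared with those of the 1000 regions nearest in wild-type rank, as a share on both sides adjusted over the 4 comparisons. The edited bases were placed by matching the sequences of the labels to the reference, and the Nanog site matched 1 base to the right of the start in the label.

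Summits within 50 kb of the outermost annotated start of each gene were summed over the members of 15 gene lists. A summit within reach of several members counted for each of them. The sums were compared with 10000 random lists drawn from coding genes in the same of 5 classes of gene density. The lists, put together from general knowledge, were core factors, naive pluripotency, formative and primed, LIF and STAT3 targets, Wnt targets, ERK feedback, trophectoderm, primitive endoderm, mesendoderm, neuroectoderm, fibroblast, housekeeping, liver, muscle and heart, and blood and immune. All 238 members were matched in the annotation. Named genes are all core factors, for each other list the 4 members bound by most factors and then with most summits, up to 3 control genes with no summit, the genes nearest the 3 peaks of highest signal in each of the 7 lists and the genes nearest the 10 regions of highest mean rank over all 7 lists, and the gene around the edited sites.

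The overlap and gene list methods were tested on simulated data: 4 of 4 simulated odds ratios lay inside their 95% interval, 5 of 5 planted gene lists were recovered and 0 of 10 other lists were called. Alternatives used windows of 50 bp around summits in place of peaks, the upper 50% of each list, lists of equal length, overlap of at least 50%, the union of all 7 lists, regions outside promoters, other motif windows, sides and mismatch numbers, starts within 500 bp, all genes, gene windows of 10 and 100 kb, no matching on gene density, the number of members with a summit, the −log10 p value for ranks, 300 neighbours and regions ranked for each mutant alone. Peaks with signal above 40 left out and motif matches outside soft-masked repeats were added after the data were seen.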

Results

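Peak lists were compared for 7 pluripotency factors mapped by ChIP-nexus in mouse R1 embryonic stem cells: Oct4, Sox2, Nanog, Klf4, Esrrb, Pbx and Zic3. Oct4, Sox2 and Nanog were also mapped by ChIP-seq, and Nanog and Sox2 were mapped again in wild-type cells and in lines carrying base changes in a Sox2 motif or a Nanog motif within an intron of Btbd11. The first lists held 25849 peaks for Oct4, 10999 for Sox2, 56459 for Nanog, 57601 for Klf4, 15057 for Esrrb, 17618 for Pbx and 46741 for Zic3. Each group had 1 list and no replicates, and sequencing depth was unknown, so tests were made over regions, genes or motif matches and not over replicates, and intervals cover counting error only. The authors' per-peak values were used only to describe or rank peaks within a list.

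Sox2 and Oct4, factors at the centre of the stem cell network, were found mostly at regions also called for Nanog and Klf4. Nanog and Klf4 also had the longest lists, and these shares depend on list length. Of the Sox2 regions, 89.8% were also called for Nanog, 83.8% for Oct4, 83.0% for Klf4 and 71.6% for Zic3. Oct4, which binds DNA as a partner of Sox2, was found with Klf4 at 73.3% of its regions and with Nanog at 66.2%, and with Sox2, which had the shortest list, at 35.7%. Esrrb, a nuclear receptor, met Klf4 at 73.8% of its regions. With all lists held to 9497 peaks, Oct4 regions from ChIP-seq met Nanog at 42.2%, Klf4 at 30.5% and Sox2 at 57.5%. Sox2 regions from ChIP-seq then met Nanog at 51.7%, Klf4 at 31.4% and Oct4 at 55.3%. Only 97 Sox2 regions (0.897%) were called for no other factor, against 9.29% for Oct4, 17.2% for Esrrb, 26.7% for Zic3 and 37.2% for Nanog.

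Every one of the 21 factor pairs met more often than independent placement would give, each tested within the regions of the other 5 factors. Oct4 and Sox2 had the largest odds ratio, 32.2 (95% interval 30.5 to 34.1), followed by Sox2 and Nanog at 20.8 (19.5 to 22.3) and Klf4 and Esrrb at 13.5. Klf4 joined Oct4 at 9.21, Sox2 at 9.11, Zic3 at 7.55 and Pbx at 7.34, while Oct4 and Nanog stood at 6.50. Nanog and Pbx had the lowest value, 2.48 (2.38 to 2.58). Adjusted p was at the smallest value written, 1e-300, for all 21 pairs. When the regions of all 7 lists were used, Nanog with Klf4 and Nanog with Pbx fell below independence, at log2 odds ratios of −0.68 and −0.58, because every region of such a union holds at least 1 factor.

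**Figure D1:**
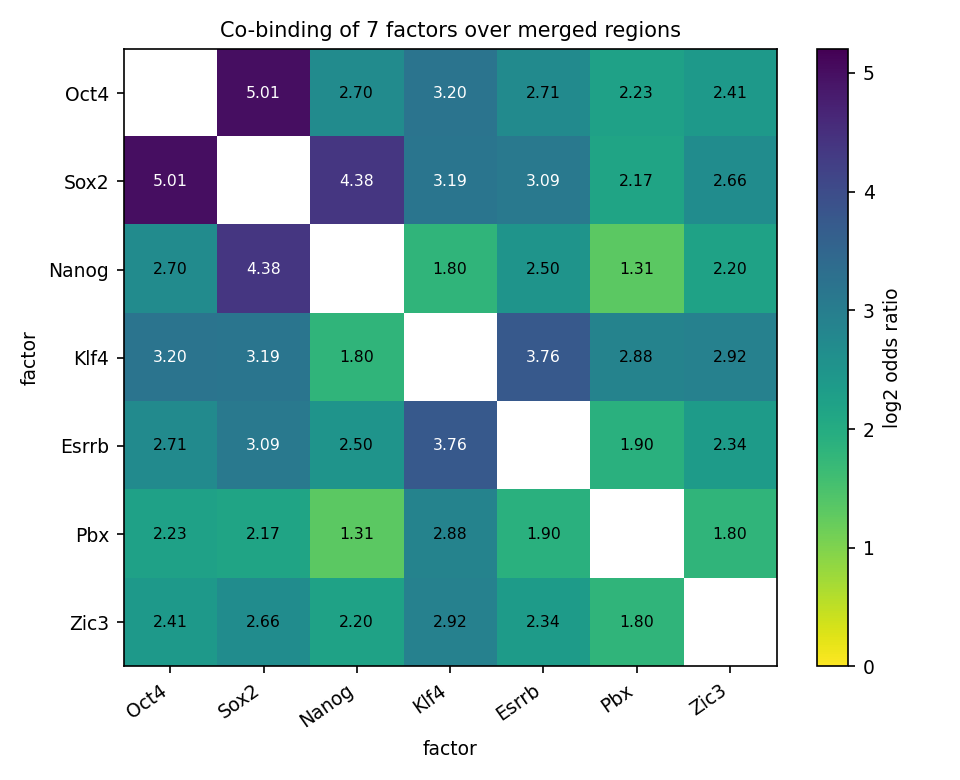
Log2 odds ratio of co-binding for each pair of the 7 factors, tested in the regions of the other 5.

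All 7 factors met at 1676 merged regions, and Oct4, Sox2, Nanog and Klf4 met at 7253. The product of the shares of each factor over the 112109 regions would give 5.18 and 611. The observed numbers were 324-fold and 11.9-fold higher, with 79.4-fold to 462-fold and 10.4-fold to 15.9-fold under the alternatives. Every region of this union holds at least 1 factor, so independent placement is not possible there. The folds therefore describe these lists and are not a test. Most regions, 60994 or 54.4%, were called for a single factor. The strongest peak in each of the 7 lists was the same intergenic region, on chromosome X from 143482914 to 143483208 in the Sox2 list, 35532 bp from the start of Pak3, a gene for a p21-activated kinase. Other leading peaks lay nearest Gm3376 on chromosome Y, Gm15319 on chromosome 8, Zfp986, C130026I21Rik, Gm10139, Gm10324 and Htr2c, and inside an intron of Lama1, a laminin gene. Of the 10 regions ranked highest across all 7 lists, nearest Pak3, Gm15319, Lama1, Tnc, Sel1l, Cldn34d, Tcerg1l, Zfp991, 4930467E23Rik and Limd1, 5 consisted mostly of sequence present more than once in the reference. With only the upper 50% of each list kept, 263 regions still held all 7 factors and 3118 held Oct4, Sox2, Nanog and Klf4.

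**Figure D2:**
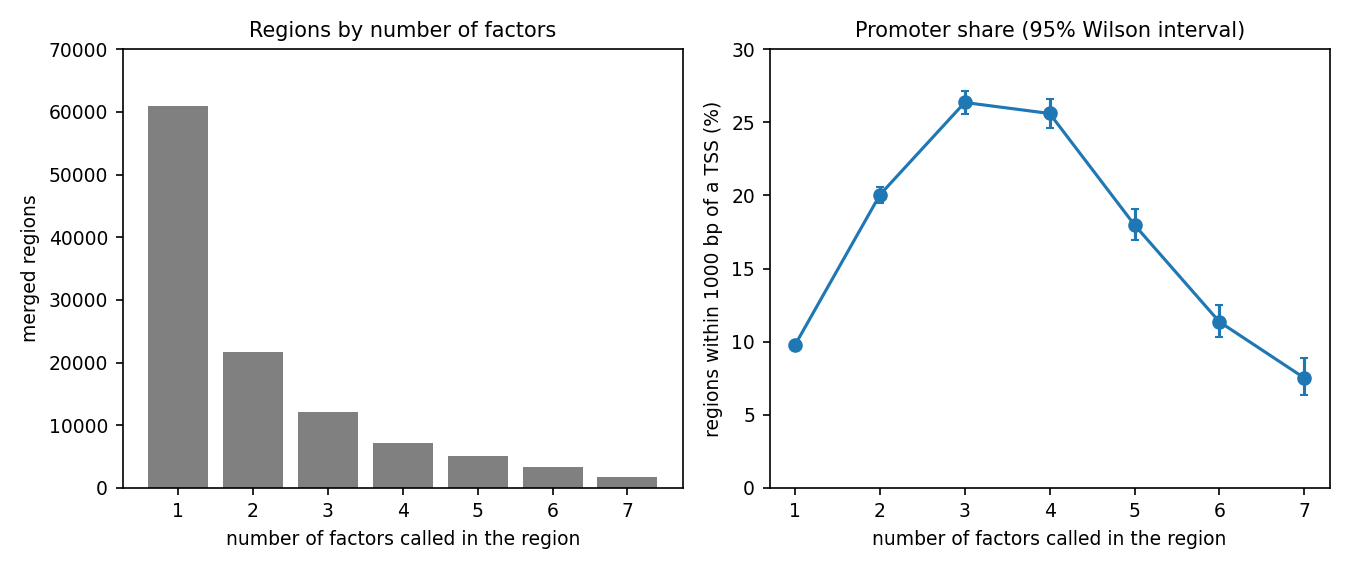
Number of merged regions by how many of the 7 factors were called there (left), and the share of those regions within 1000 bp of a coding transcript start with 95% intervals (right).

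Klf4, Pbx, Oct4 and Zic3 lay at promoters more often than Sox2, Nanog and Esrrb. Summits within 1000 bp of a coding transcript start made up 23.4% of the Klf4 list, 22.7% of Pbx, 19.8% of Oct4 and 18.6% of Zic3. Esrrb stood at 9.64%, Nanog at 6.32% and Sox2 at 6.19%, and 54.1% of Sox2 summits were intergenic. Against the other 6 lists, the log2 odds ratio was 0.95 for Klf4 and 0.68 for Pbx, and it was −0.89 for Esrrb, −1.59 for Sox2 and −1.82 for Nanog. Zic3 stood at 0.32 and Oct4 at 0.43, with adjusted p of 1.8e-60 and 2.7e-66. The Oct4 value became −0.32 when only the upper 50% of each list was used.

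Oct4, Sox2, Klf4, Esrrb, Pbx and Zic3 summits carried the DNA motif of their own factor far above the sequence 1000 bp away. Nanog summits did so with a lower fold. The Zic3 motif lay within 50 bp of 21.2% of Zic3 summits, 23.1-fold above the moved window, and the Pbx motif lay near 19.2% of Pbx summits, 109-fold above it. Klf4 stood at 14.7% (15.3-fold) and Esrrb at 14.0% (42.2-fold). The composite Oct4-Sox2 motif was near 6.30% of Oct4 summits (37.9-fold) and 8.97% of Sox2 summits (51.9-fold), and the Sox2 motif alone was near 3.89% of Sox2 summits. For Nanog, the Nanog motif was near 4.82% of summits, 3.04-fold above the moved window. The Nanog motif is the shortest, with 414100 matches in the genome against 65995 for Pbx, so folds cannot be compared between motifs. Of 128 combinations of list and motif, 117 exceeded the moved window and 0 fell below it.

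Motif shares rose with peak strength for Oct4, Zic3 and Pbx. They rose less for Nanog, Klf4 and Esrrb, and for Sox2 with the Sox2 motif alone. From the lowest to the highest signal decile, the Oct4-Sox2 motif rose from 0.929% to 17.8% of Oct4 summits. The Pbx motif rose from 7.44% to 27.1%, and the Zic3 motif reached 45.0% in the highest decile. Nanog moved from 4.18% to 6.61% and Sox2, with the Sox2 motif alone, from 2.55% to 4.91%. With the Oct4-Sox2 motif, Sox2 summits rose from 4.46% to 15.5%. Motifs of other factors also lay near summits: the Klf4 motif was near 5.44% of Pbx summits and the Zic3 motif near 5.56% of Sox2 summits. Whether Klf4 or Zic3 was bound at those matches was not tested, and the moved windows were not matched for base composition. The motif of CTCF, an architectural protein not mapped here, was near 1.21% of Klf4 summits and 1.14% of Zic3 summits, while its 0.104% of Nanog summits did not exceed the moved window (adjusted p 0.26).

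**Figure D3:**
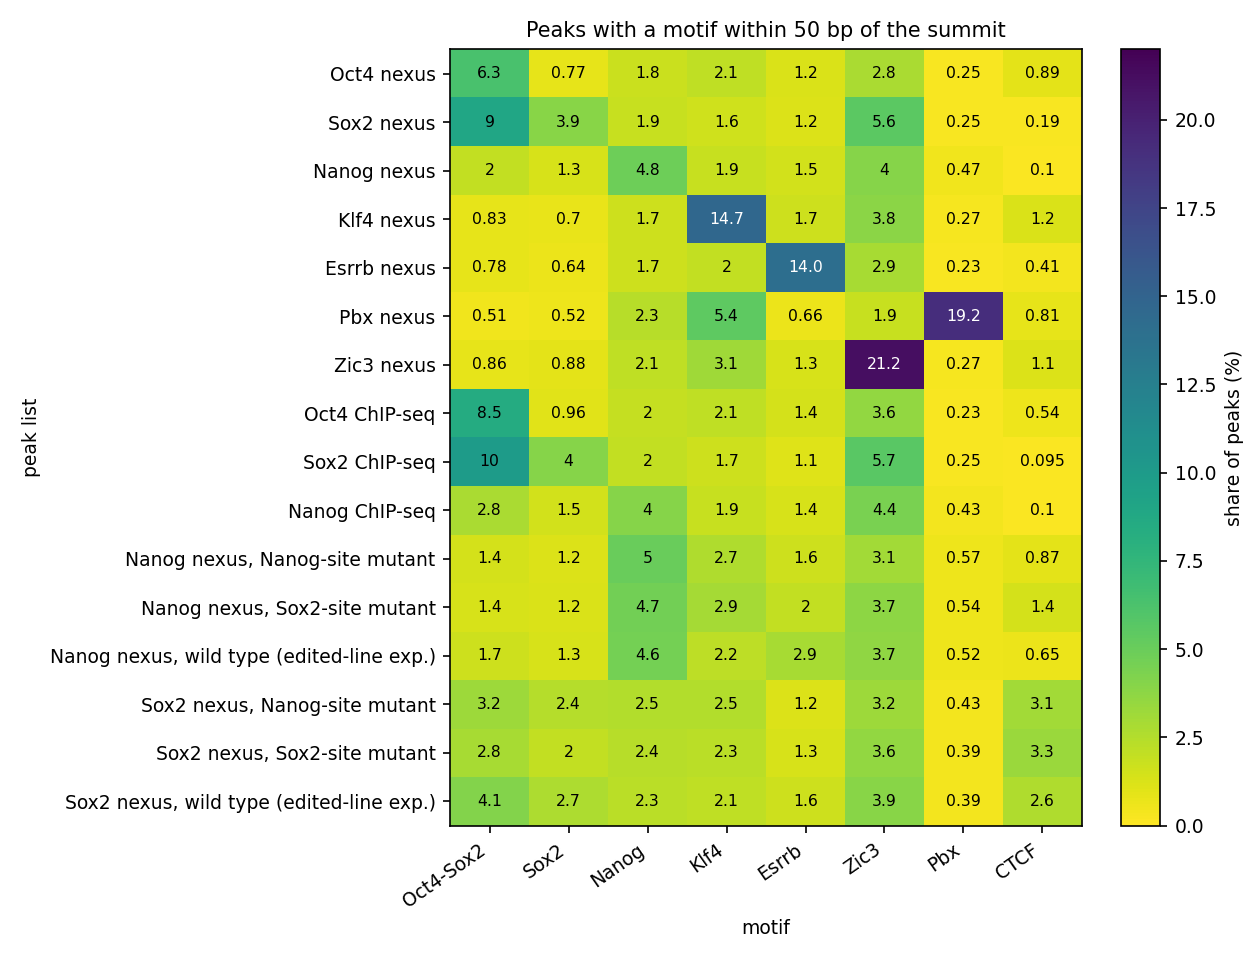
Share of peaks with each motif within 50 bp of the summit, for the 16 lists and 8 motifs.

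Nanog motifs near Nanog summits were examined for helical spacing, that is, for an excess of pairs at multiples of the turn of the DNA helix. Spectral power at periods of 10 to 11 bp was 1.11 times the mean over periods of 5 to 20 bp for Nanog motifs in the Nanog list. Shifting each motif at random by up to 10 bp gave a median of 0.655 and a permutation p of 0.084. Adjusted over 19 tests it was 0.42, so no spacing preference was called for Nanog. Matches in sequence were tested and not bound sites. The Nanog windows held 44264 matches and the moved windows 33082, so many matches may be background. A spacing of bound sites could therefore be missed. Windows of 200 bp raised the Nanog value to 2.05 with an adjusted p of 0.095, and the moved windows stood at 0.387. Among the 19 tests only that of Zic3 motifs at summits of Zic3, a zinc finger factor, was called. The value, also with up to 1 mismatch, was 3.04, with 11 bp the strongest of the periods searched around the helical turn. The permutation p was 0.000999, the smallest possible with 1000 random sets, adjusted to 0.019. Moved windows, exclusion of repeats and other alternatives were not run for Zic3, so its value was not set against background sequence.

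ChIP-seq and ChIP-nexus found largely the same Oct4, Sox2 and Nanog regions. Of the ChIP-seq regions, 80.8% for Oct4, 78.7% for Sox2 and 90.0% for Nanog were in the ChIP-nexus list of the same factor, with odds ratios of 76.6, 214 and 74.3. In the other direction, 58.4% of Oct4, 67.2% of Sox2 and 61.9% of Nanog regions from ChIP-nexus were in the ChIP-seq list. Sox2 regions from ChIP-seq met the longer Nanog list even more often, at 91.5%. With all lists held to 9497 peaks, each factor met its own list best, at 74.6% for Oct4, 74.1% for Sox2 and 74.8% for Nanog.

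Nanog and Sox2 summits lay nearer to a motif in ChIP-nexus than in ChIP-seq, and Oct4 differed little. At 2027 shared Nanog peaks with a single Nanog motif, the median distance was 7 bp in ChIP-nexus and 29 bp in ChIP-seq, and the ChIP-nexus summit was the closer at 72.0% of peaks (95% interval 70.0 to 73.9, adjusted p 5.1e-88). For Sox2, measured to the Oct4-Sox2 motif at 859 peaks, the medians were 8 and 17 bp, with ChIP-nexus closer at 68.2% (adjusted p 3.3e-26). Oct4 had medians of 11 and 15 bp to the same motif and ChIP-nexus was closer at 53.4% of 1525 peaks (50.9 to 55.9, adjusted p 0.0094). How summits were placed is not given in the sources used here, so the assay cannot be told apart from the peak caller.

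Nanog and Sox2 were profiled again with other antibodies in the edited-line experiment, and the first lists were found almost whole in the new ones. Of the first Nanog regions, 95.2% were in the new wild-type Nanog list of 105037 peaks, and 98.0% of the first Sox2 regions were in the new Sox2 list of 69414 peaks. The reverse shares were 51.2% for Nanog and 15.8% for Sox2, with odds ratios of 45.1 and 128. Antibody and experiment changed together, so neither can be named as the source of the longer Nanog and Sox2 lists.

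Most wild-type Nanog and Sox2 regions were called again in the lines with changed bases in the Btbd11 intron. Of the wild-type Nanog regions, 86.7% were called again in the Sox2-site mutant and 90.3% in the Nanog-site mutant. Of the wild-type Sox2 regions, 89.3% and 91.3% were called again. In the other direction, 73.6% and 70.2% of the Nanog regions and 67.1% and 66.2% of the Sox2 regions of the Sox2-site and Nanog-site mutants were in the wild-type list. The mutant lists were longer than the wild-type lists, with 124143 and 135483 Nanog peaks and 93352 and 95658 Sox2 peaks.

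At the edited locus in Btbd11, a gene for an ankyrin repeat and BTB domain protein, a Nanog and a Sox2 peak covered the edited sites in wild type and in both mutant lines. The Sox2 site lies on chromosome 10 from 85539634 to 85539643 and reads CCTTTGTTCC, changed by T4A and T5G to CCTAGGTTCC. The Nanog site lies from 85539757 to 85539765 and reads CTGATGGCT, changed by T2G and A4C to CGGCTGGCT. Positions of the changes are counted from the first base of each site. The sites are 113 bp apart, and the nearest coding transcript start, that of Btbd11, is 58766 bp away. The reference sequence around them, from 85539604 to 85539795, is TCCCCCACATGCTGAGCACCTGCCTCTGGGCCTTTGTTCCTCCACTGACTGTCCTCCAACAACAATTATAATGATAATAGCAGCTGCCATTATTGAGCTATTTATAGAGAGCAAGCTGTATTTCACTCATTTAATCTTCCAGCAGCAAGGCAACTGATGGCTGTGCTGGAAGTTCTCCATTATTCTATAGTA. Oct4, Klf4, Esrrb, Pbx and Zic3 peaks also covered both sites, with the Pbx summit at 85539636 on the Sox2 site and the Oct4, Klf4 and Esrrb summits to its right, at 85540090, 85540013 and 85540098.

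Nanog lost rank at the Btbd11 locus when the Sox2 motif was changed, and the region lost little Nanog rank when the Nanog motif was changed. Among 86850 Nanog regions called in all 3 lines, the locus stood at percentile 56.1 in wild type and 3.20 in the Sox2-site mutant, a shift of −52.9 points. Only 4 of 1000 neighbouring regions of similar rank shifted as far down, a share of 0.00999 on both sides, adjusted to 0.040. Ranked by the authors' −log10 p, the fall was smaller, from percentile 96.9 to 73.4, a shift of −23.4 points (adjusted share 0.0080). In the Nanog-site mutant Nanog stood, by signal, at percentile 48.1, a shift of −7.97 points (adjusted share 0.78). Sox2 moved by −1.77 points in the Sox2-site mutant and 1.04 points in the Nanog-site mutant (adjusted share 0.78 for each). Summits moved in the Sox2-site mutant, by 247 bp for Nanog from 85539643 to 85539890 and by 363 bp for Sox2 from 85539634 to 85539997, and 3.03% and 2.05% of peaks of similar width moved at least as far. In the Nanog-site mutant the Nanog summit moved by 17 bp and the Sox2 summit by 1 bp. Each region was ranked by its strongest peak. In the Sox2-site mutant the summit of that Sox2 peak, at 85539997, lay away from the Sox2 site. The Sox2 ChIP-seq list had a separate peak there, with its summit at 85540037. The small rank shift of Sox2 therefore does not show whether Sox2 stayed at the changed motif. Likewise, the wild-type Nanog summit, at 85539643, lay at the Sox2 site and away from the Nanog site. The small Nanog shift in the Nanog-site mutant thus does not show whether Nanog left its own changed motif. With 1 list for each line, the shares place the Btbd11 locus among its neighbours and do not measure variation between cultures.

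**Figure D4:**
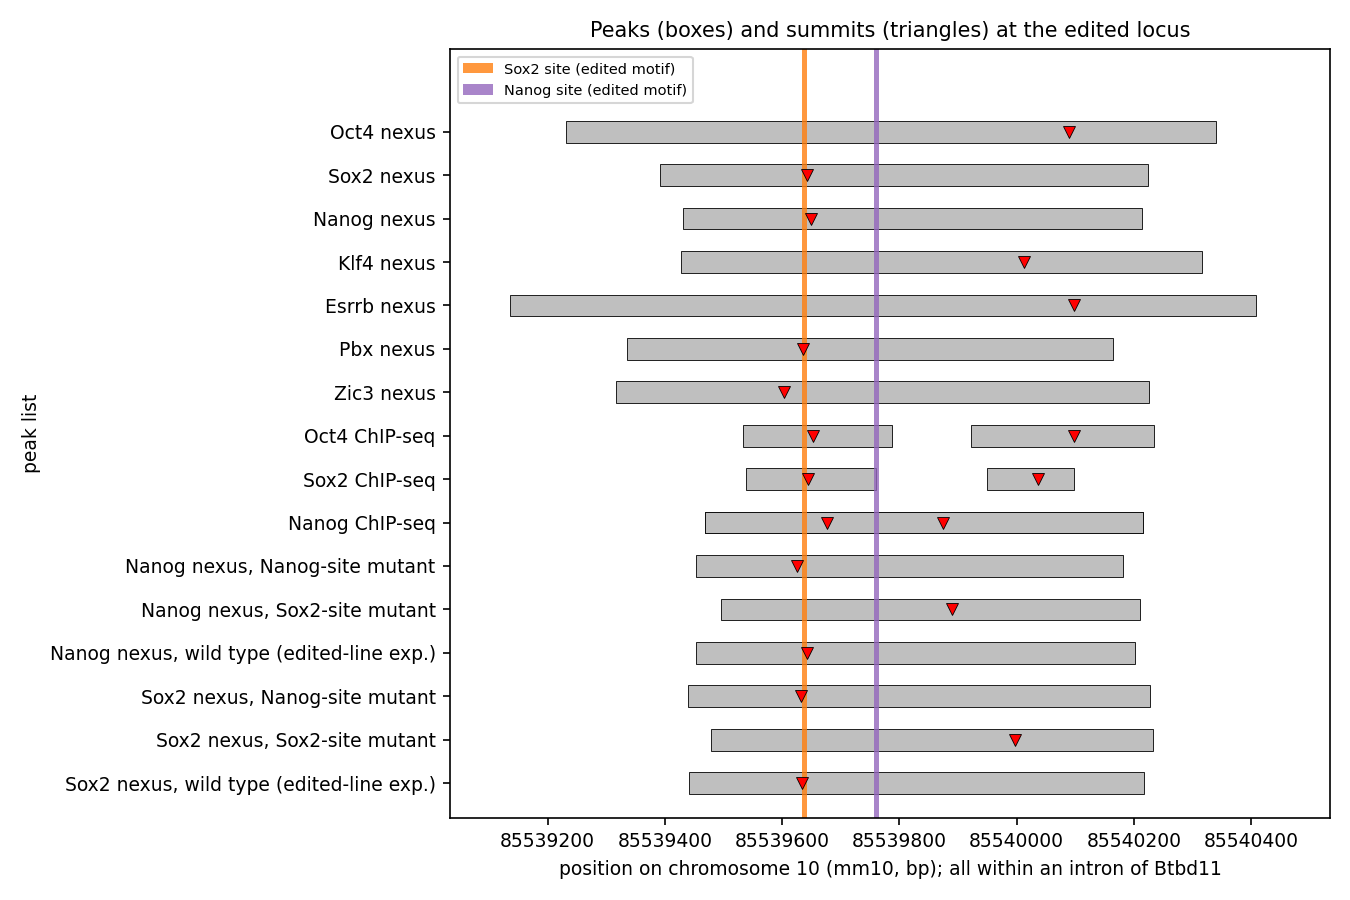
Peaks and summits of the 16 lists around the edited Sox2 and Nanog sites in the Btbd11 intron.

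Genes of naive pluripotency gathered more summits of every factor than random genes of equal gene density. Within 50 kb of their transcript starts, the 30 members had 4.56 times the random median for Sox2, 4.34 for Esrrb, 3.00 for Oct4, 2.86 for Nanog, 2.84 for Pbx, 2.53 for Zic3 and 2.43 for Klf4, with an adjusted p of 0.0016 each. Summits within reach of neighbouring members of a list counted for each of them, and random lists were not matched for such neighbours. Ratios may thus be too large and p too small for lists with neighbouring members, and by how much was not tested. All 7 factors were present at 27 of the 30 naive genes, compared with 25.8% of all coding genes. Jarid2, a Polycomb cofactor, had 68 summits; Tbx3, a T-box factor of the naive state, had 63; Fgf4, the growth factor that starts ERK signalling, and Tet2, an oxidase of methylcytosine, had 58 each. The genes of the factors themselves were also above random for all 7 factors: Nanog had 63 summits, Pou5f1, which encodes Oct4, had 54, Sox2 had 45, Zic3 had 32, Pbx2 had 22 and Pbx1 had 20. Esrrb had 19 summits and none of Sox2 or Pbx, Klf4 had 17 and none of Pbx, and Pbx3 had 16 and none of Esrrb. Only the outermost annotated start of each gene was used, so summits near its other starts may be missed. For the list of core factors the alternatives left between 1 and 7 factors above random. There were 3 when gene density was not matched and 3 with the upper 50% of each list.

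Targets and feedback genes of LIF, ERK and Wnt signalling and genes of formative and primed cells were above random for 4 or more factors. The LIF and STAT3 list was above random for all 7 factors, from 2.42 times for Oct4 to 3.57 for Sox2, with 70 summits at Socs3, the feedback inhibitor of JAK signalling, 60 at Pim1, 54 at Junb and 45 at Gjb3. ERK feedback genes were above random for 6 factors, all but Pbx, with 83 summits at Etv5, an ETS factor, 54 at Spry2, 37 at Spred2 and 34 at Spry4, which restrain receptor tyrosine kinases. Wnt targets were above random for Oct4 (2.14), Nanog (2.02), Klf4 (2.02) and Zic3 (1.87), with 55 summits at Tcf7l1, a repressor of Wnt targets, 44 at Cdx1, 34 at Tnfrsf19 and 33 at Notum. Genes of formative and primed cells were above random for all 7 factors, led by Fgf15 with 61 summits, Otx2 with 53, Zic5 with 46 and Foxd3 with 44. The windows of Fgf15 and of Fgf4, which is in the naive list, share ground. Under the alternatives between 2 and 7 factors were above random for the LIF and STAT3 list, 2 and 6 for ERK feedback, 2 and 6 for Wnt targets and 0 and 7 for formative and primed genes.

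Trophectoderm genes were above random for Nanog, Klf4, Esrrb, Pbx and Zic3, while Oct4 and Sox2 were not called, with 73 summits at Tfap2c, 49 at Tead4, 38 at Tfap2a and 35 at Hand1, all factors of early trophoblast. Mesendoderm genes were called above random for Nanog (1.71) and Zic3 (1.68), with 40 summits at Gsc, 30 at T, the brachyury gene, 27 at Fgf8 and 25 at Cdx4. Housekeeping genes were above random for Oct4, Klf4, Esrrb, Pbx and Zic3, with 48 summits at Hmbs, 45 at Gapdh, 44 at Rpl13a and 43 at Ywhaz. Muscle and heart genes were below random for Sox2, with 2 summits against a random median of 10 (adjusted p 0.038), a call that none of the 5 alternatives kept (adjusted p 0.053 to 0.81). Mb, for myoglobin, had 35 summits and Tnni3, for troponin, had 30, while Tnnt2 and Ryr1, with 27 each, were bound by 6 factors. Under the alternatives between 0 and 4 factors were above random for trophectoderm genes, 0 and 3 for mesendoderm genes and 0 and 5 for housekeeping genes. No difference between these lists was tested.

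Primitive endoderm, neuroectoderm, fibroblast, liver and blood genes were above random for 0 factors. Single genes among them were well bound: Tubb3, a neuronal tubulin, had 45 summits, Fn1, for fibronectin, had 44, Cd68 had 41, Gata1 and Hpd had 38 each and Apoa2 had 36. Sparc with 33 summits, Hnf4a with 32, Lama1 with 31 and Lamb1 with 23 led the endoderm genes, and Nes with 32, Rax with 25 and Pax6 with 22 were, with Tubb3, the neuroectoderm genes bound by all 7 factors. Col1a1, with 36 summits, Thy1, with 20, Fgg, with 16, and Apoa1, with 15, were bound by 6 factors, and Col3a1, Cd79a and Cd19 had 11, 28 and 27 summits. Dcx, for doublecortin, Dcn, for decorin, and Serpina1a, for an antitrypsin, had 0 summits of any factor. In all, 50 of 105 combinations of gene list and factor were above random and 1 was below; counting only whether a gene had a summit left 14 above random, 7 of them the naive list.

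**Figure D5:**
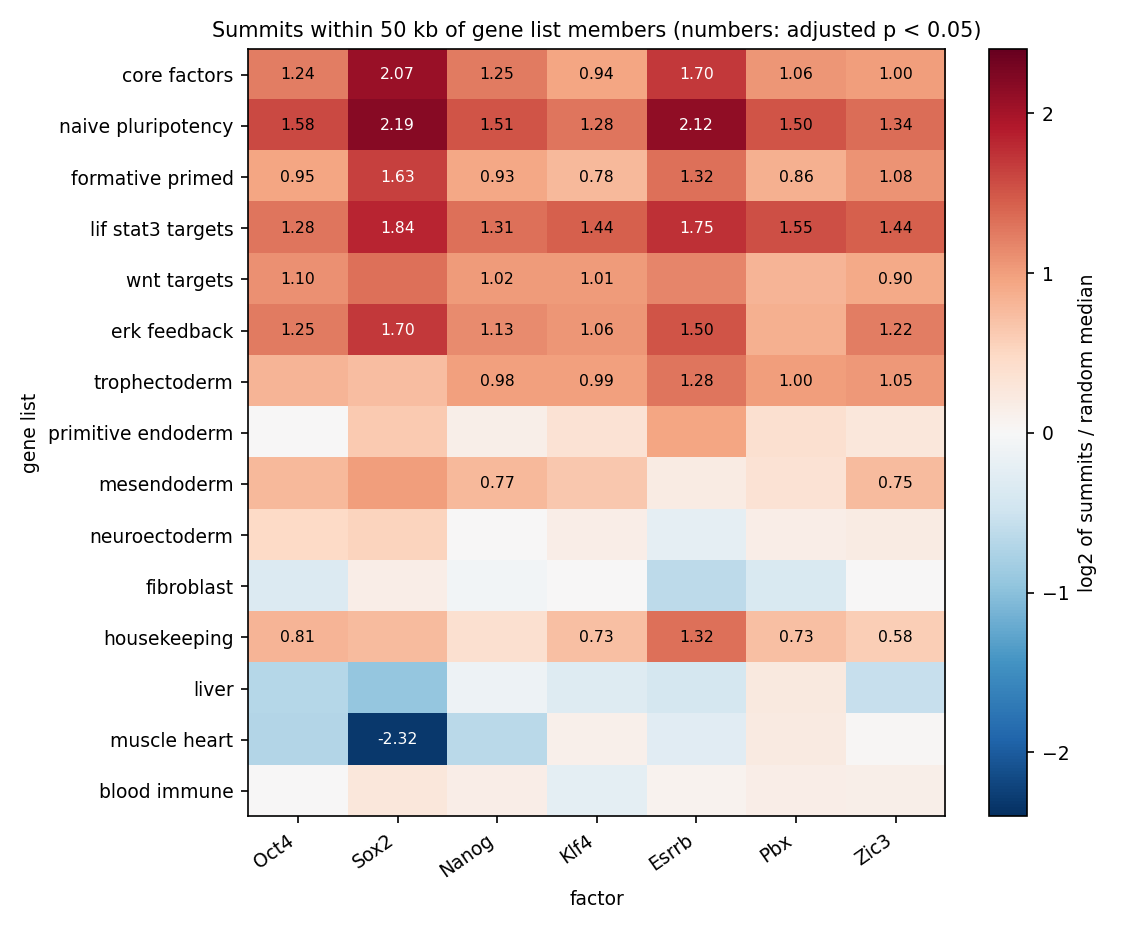
Summits of each factor near the members of each gene list, as the log2 ratio to the median of random lists of equal gene density, with values printed where the adjusted p was below 0.05.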

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

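The tests of motif enrichment at equal list length (16 tests), the tests of the CTCF pattern against the Nanog list and the use of all tests of the Btbd11 locus in this part were chosen after the results were seen.

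Nanog at the Btbd11 locus stood out because it behaved differently in the mutant lines: its shift in the Sox2-site mutant was lower than in the Nanog-site mutant by a difference of −44.9 points. For this difference the adjusted share of neighbours was 0.016. The shift of Nanog from wild type in the Sox2-site mutant was −52.9 points. Its adjusted share of neighbours shifted as far was 0.0400, and 0.0080 to 0.0400 under the alternatives, so most neighbours in these lists shifted less. These are the values by which the shift was called. They do not set chance aside, since each line had 1 list and spread between cultures was not measured. Changed bases may lower the number of aligned reads, and the shift of −7.97 points in the Nanog-site mutant could not settle this, because the wild-type Nanog summit, at 85539643, lies at the Sox2 site and away from the changed bases of the Nanog site. A dependence of Nanog on the Sox2 motif, and any other difference between the edited lines, had no test apart from the Nanog shifts themselves. Both remain open, since each line had 1 list.

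The CTCF motif in the Sox2 lists of the edited-line experiment was near 2.61% of wild-type summits, while the first Sox2 list held 0.191%. A longer list with weaker peaks is a candidate explanation, because the strongest 10999 peaks of the new list held only 0.209%, close to the first list. This shows where peaks with the motif rank and not why they were called. Of these peaks, 1.38% were in the first Sox2 list, against 15.9% of peaks without the motif. The Nanog-site and Sox2-site mutant Sox2 lists held 93.5% and 94.3% of them, against 90.8% and 88.9%. Antibody and experiment changed together here too and cannot be told apart. Promoter peaks are an unlikely source, as 2.91% of peaks away from promoters carried the motif. Cells or library steps shared with the Nanog lists remain open: the whole wild-type Nanog list of the experiment held 0.646%, above the 0.104% of the first Nanog list and below the Sox2 share, and the mutant Nanog lists held 0.873% and 1.42%, while the strongest 10999 and 69414 wild-type Nanog peaks held 0.109% and 0.376%. No biological explanation was tested.

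The first Nanog list and the wild-type Nanog list of the edited-line experiment differed at equal length in the log2 enrichment of the Esrrb motif by 0.97 (from 1.48% to 2.47% of summits, adjusted p 4.4e-07) and of the CTCF motif by 1.56 (from 0.104% to 0.253%, adjusted p 0.00047), values that stood out because they differed between the groups. At full length the Esrrb motif was near 2.89% of summits in that wild-type list, 2.02% in the Sox2-site mutant and 1.64% in the Nanog-site mutant. The mutant Nanog lists of the same antibody and experiment thus lay closer to the 1.48% of the first list. These lists differ in length, which also moves the share, and no value at equal length was taken for the mutants.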

How the results depend on the processing

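No paired analysis was possible because each group had 1 list. Under 147 alternatives for co-binding pairs, 144 left the call as it was. With the union of all 7 lists, Nanog with Klf4 became −0.68 and Nanog with Pbx −0.58 in log2 odds ratio, because such a union forces the factors of a pair apart, and Nanog with Zic3 was no longer called. Regions with Oct4, Sox2, Nanog and Klf4 numbered 3118 with the upper 50% of each list, 1948 with lists of equal length and 4479 with overlap of at least 50%, and regions with all 7 factors numbered 263, 260 and 851, and 779 with summit windows. The upper 50%, equal length and summit windows keep fewer or shorter peaks, and overlap of at least 50% sets a stricter rule for a factor to count, so lower numbers follow by construction. The Nanog spacing ratio was 2.05 with windows of 200 bp, and the cause was not tested. The Oct4 promoter preference became −0.32 in log2 odds ratio with the upper 50% of each list, and the cause was not tested; the other 20 of 21 location alternatives kept the call. Sox2 at the Btbd11 locus in the Nanog-site mutant shifted by −0.315 points when ranked by −log10 p, and the cause was not tested; the other 11 of 12 locus alternatives kept the call. Calls for gene lists above random dropped to 14 when members with at least 1 summit were counted, and the cause was not tested. Calls below random numbered 0 with that count, with the upper 50%, with no matching and with 100 kb, and with 10 kb the 1 call was in the blood and immune list, so no alternative kept the call of Sox2 at muscle and heart genes; the cause was not tested. The naive pluripotency list kept all 35 of its calls, and the other called combinations of list and factor kept 137 of 220, with 83 weaker. All alternatives kept the call for the 9 assay, 6 antibody, 12 mutant line, 21 own motif and 9 summit distance comparisons. Shares of regions found again moved in 26 of 27. Among the 54 combinations of gene list and factor that were not called, 52 of 270 alternatives had the other sign and 7 passed the threshold, in 5 combinations.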

Other observations

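All tests in this part, from naive against housekeeping genes to the strongest regions, were chosen after the results were seen. Naive pluripotency genes had more summits per gene than housekeeping genes for all 7 factors, and the difference was called for Sox2 and Nanog. The 30 naive genes had on average 2.73 Sox2 summits and 8.57 Nanog summits each. The 16 housekeeping genes, such as Gapdh and Hmbs, had 1.06 and 4.19 (permutation, adjusted p 0.00077 each). Summits within reach of neighbouring members counted for each of them here too. Klf4 (adjusted p 0.35), Pbx (0.19), Esrrb (0.086), Oct4 and Zic3 (0.085 each) were not called, and no difference between factors was tested. The largest numbers of summits of all coding genes were at Gm15319, with 134, and at Hist1h3g in the histone cluster on chromosome 13, with 113, followed by its neighbours Hist1h2af, Hist1h2bh and Hist1h3f, with 109 each, and by Gm21887 on chromosome X and Zfp992 on chromosome 4, with 107 each. The histone genes lie within reach of the same summits, and how much of these windows is repeated sequence was not measured. Promoter regions were most frequent among regions with 3 factors, at 26.4%, and made up 7.52% of regions with all 7.

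Esrrb and Zic3 occupied motifs in soft-masked repeats about as often as such motifs occur in the genome. Of Esrrb motifs near Esrrb summits, 46.0% were soft-masked, against 44.9% in the genome, and of Zic3 motifs 26.4% against 23.8%. Nanog motifs near Nanog summits were soft-masked in 11.1% of cases against 37.6%.

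The 10 regions ranked highest across all 7 lists, led by the region nearest Pak3, may reflect multi-copy sequence, since 5 of the 10 had over 50% of their 32-base words more than once in the reference, compared with 5.04% of the other 1666 regions. Binding at the factors' own motifs, with the Oct4-Sox2 motif taken for Oct4 and Sox2, could be neither kept nor set aside, at 2.86% of peaks against 6.47% (Fisher p 0.33). The outermost of the 7 summits lay a median of 36.5 bp apart, against 237 bp in the other regions, which could come from signal that does not depend on the antibody. The Pak3 region itself had only 12.5% repeated words, and 5 of the 10 regions were in a ChIP-seq list, against 95.5% of the others.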
